A study of Homo sapiens with 15 samples.

How the data were processed

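RNA of human mesenchymal stem cells from bone marrow was sequenced after 7 days with 1 of 5 ions or without added ions, in 15 libraries that fall into 6 groups. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and aligned to hg38 with STAR. The authors deposited 1 table of RPKM values, reads per kilobase of gene length and megaread, for 11328 genes, with replicates kept apart. The counting tool, the annotation and the gene filter behind the table are not given in the sources used here. Every listed gene had an RPKM of 1 or more in at least 2 libraries. All columns of values were used (0 left out). Gene identifiers were Entrez numbers, of which 11318 were matched to RefSeq annotation of GRCh38.p14 for coordinates, and 11270 of the genes were protein coding. GENCODE 29 gave GC content and length for 11306 genes (99.8%).

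Once each library's scaling factor was removed, the RPKM values of a gene stood in ratios of whole numbers. From these ratios the reads behind each value were recovered for 11327 genes (100.0% after rounding; FN1 was the exception), within a relative tolerance of 1e-10. They came to 21.5 to 37.1 Mreads per library. The median gene had 618 reads per library. For genes with few reads, ratios are given with an exact conditional 95% interval (Clopper-Pearson), which covers counting error only.

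Leaving out 8 sex-linked genes left 11320. Values were taken as log2(RPKM + 1), a pseudocount of 1, without further scaling, which understates changes of genes near an RPKM of 1. They were fitted with limma 3.58.1 in R 4.3.3, with a trend of variance on level and 1 spread shared by all 6 groups. Each ion was compared with control, each pair of ions with each other, and the 6 groups together by limma's moderated F test. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Groups of 2 or 3 libraries are too small for permutation tests to reach this threshold.

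A set of 39 gene lists was fixed before the data were examined, as were the comparisons, the rule for naming genes and the alternatives not stated as added. Of these lists, 36 had genes in the table and 31 had the 5 or more needed for a test. Mitochondrially encoded genes, nuclear-retained RNAs and erythroid markers had 0 genes in the table, endothelial markers had 2, blood and immune markers and neural genes 3 each, and skeletal and cardiac muscle genes and epithelial markers 4 each. Lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. The fry test asked whether a list's genes moved on balance one way without comparing them with other genes. Members were also counted after adjusting p-values over the list alone.

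Genes named for an ion were the 8 largest increases and the 8 largest decreases among genes past the threshold whose ion libraries all lay beyond both control libraries, up to 4 members of each list with the smallest p-values, and any member of the metallothionein, copper, iron, osteogenic, chondrogenic and adipogenic lists. Where fewer than 3 genes passed in a direction, the 3 with the smallest p-values were named as not passing. For a pair of ions, the 3 largest in each direction whose libraries did not overlap were eligible, and for the 6 groups together the 10 genes with the smallest p-values. Not every eligible gene is named in the text, and 1 is not reported here.

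The alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean RPKM of 5 or more (8067 genes), quantile normalization, median-of-ratios scaling, a fit on the compared groups alone, the replicate number as a block, leaving out each library in turn, the estimated correlation, and fry. Alternatives added later were leaving out both Ti libraries, precision weights from recovered reads (limma's voom, 11319 genes), 4 groups without the block, a log2 change of 1 or more for counts of genes (for the overlap of ions this was fixed in advance), and median-of-ratios scaling for lists. Overlap between ions was set against 100 simulations of unchanged groups compared with 2 shared controls. In these the deviations of all 15 libraries from their group means were shuffled among the groups and given random signs.

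Whether the replicates are separate cultures is not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical. The procedure was tested on reads simulated for 11319 genes from the control means, with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale in each comparison. Of genes changed by 1, 89.6 to 97% were recovered, of those changed by 2, 98.5% or more, and of those changed by 0.5, 35.8 to 55.2%. Between 2.4 and 6.8% of calls were false. A list of 25 genes raised by 0.5 was called by camera, by camera with an estimated correlation and by fry, and 0 of 20 random lists were. The simulated noise was independent between genes. Neither the list result nor the share of false calls therefore covers genes that vary together. The simulated Ti libraries had the spread of the other groups, which is smaller than the spread seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.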

Results

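The series set out to learn how inorganic ions affect stem cell fate and signalling. Human mesenchymal stem cells from bone marrow, adherent stromal progenitors that can form bone, cartilage and fat cells, were kept for 7 days with silver (Ag, 29.95 µM), copper (Cu, 26.66 µM), platinum (Pt, 1.48 µM), tantalum (Ta, 41.45 µM) or titanium (Ti, 10.44 µM) ions, or without added ions. RNA sequencing gave 15 libraries in 6 groups: 3 libraries each for Ag, Cu and Ta, and 2 each for control, Pt and Ti. The replicate numbers of the Pt and Ti libraries differ between the labels and the table, so these libraries are called a and b here. The doses differ between ions, so every difference between ions holds for these doses. Whether the replicates came from separate cultures or donors is not given in the sources used here.

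The table lists 11328 genes as RPKM, reads per kilobase of gene length and megaread (Mread). Library totals recovered from these values lay between 21.5 and 37.1 Mreads. They were 35.3 Mreads in both control libraries, 21.5, 23.2 and 35.6 with Ag, 32.8, 29.9 and 22.6 with Cu, 28.7 and 26.7 with Pt, 27.2, 35.1 and 37.1 with Ta, and 31.4 and 29.9 with Ti. The median gene had 618 reads per library. Replicates of the control, Ag, Cu, Pt and Ta groups correlated at r = 0.993 or more across genes, with a root mean square SD of 0.119 to 0.154 on the log2 scale. Both Ti libraries correlated at r = 0.982, with an SD of 0.304. Changes below are log2 fold changes of RPKM + 1 with their SE, which shrinks the change of genes near 0, and p-values are adjusted over the 11320 genes tested. These p-values measure only the spread between these samples, and intervals on read ratios cover counting error only.

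**Figure D1:**
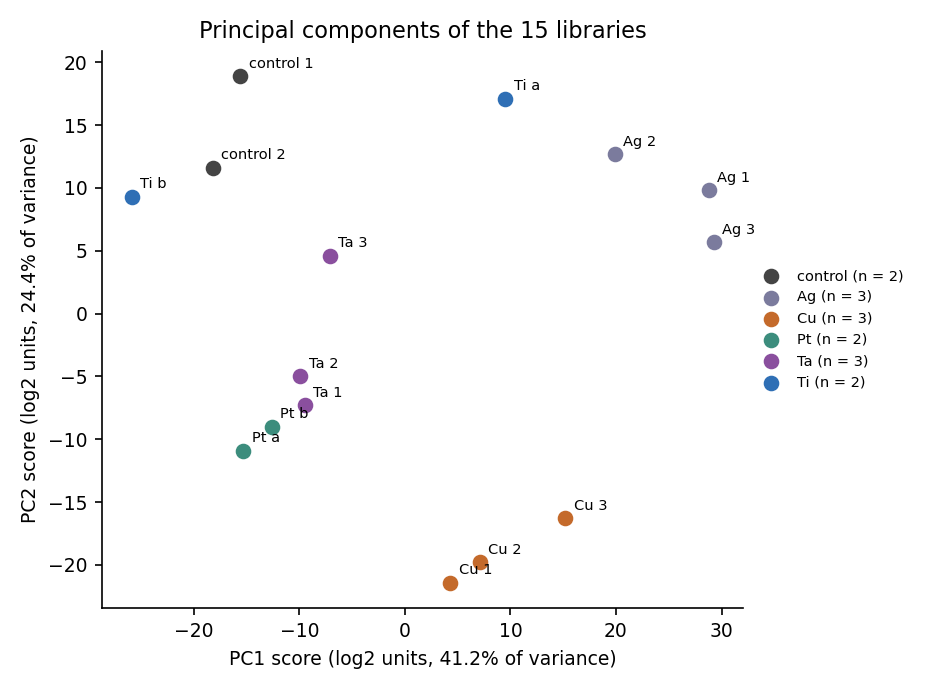
Scores of the 15 libraries on principal components 1 and 2 of log2(RPKM + 1), which hold 41.2% and 24.4% of the variance; each point is a library, coloured by group. Ag libraries lie at PC1 scores of 19.9 to 29.3, Cu libraries at PC2 scores of -21.4 to -16.3, and the Ti libraries at PC1 scores of 9.5 and -25.9.

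The comparison of Ag with control asked which genes Ag ions changed. MT1G, a metallothionein that binds metal ions (Entrez gene 4495, hg38 chromosome 16, 56666730 to 56668065), rose by 4.45 ± 0.18 with Ag (n = 3) against control (n = 2; adjusted p = 3.1e-09). Its reads went from 3 in both control libraries together to 466 in the Ag libraries, a ratio of 132 after library totals (95% interval 44.8 to 641). TM4SF20, a tetraspan membrane protein (Entrez gene 79853, chromosome 2, 227362038 to 227381647), rose from 8.74 ± 0.657 to 78.0 ± 2.01 RPKM (means with SD; adjusted p = 2.3e-07). LEP, which encodes the hormone leptin, rose by 2.51 ± 0.29, with a read ratio of 27.1 (95% interval 14.1 to 59.9). PAPPA, a protease that cleaves insulin-like growth factor binding proteins, rose by 2.02 ± 0.17 and SYNPO2, an actin-binding protein, by 2.00 ± 0.20. TXNIP, an inhibitor of thioredoxin and of glucose uptake (Entrez gene 10628, chromosome 1, 145992435 to 145996579), fell from 308 ± 70.4 to 10.3 ± 3.86 RPKM (adjusted p = 7.8e-04). CXCL12, the marrow chemokine that holds blood stem cells (Entrez gene 6387, chromosome 10, 44370165 to 44385097), fell from 46.9 ± 6.87 to 4.83 ± 3.03 RPKM. PLAT, tissue plasminogen activator, fell from 144 ± 32.7 to 25.1 ± 1.97 RPKM and the keratin KRT14 from 33.0 ± 1.69 to 5.15 ± 1.58 RPKM.

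Genes of cell division were lower with Ag. All 25 members of the proliferation list fell (25 adjusted over the list alone), with a median change of -1.75, or -1.56 relative to the median of all genes (adjusted p = 6.6e-15 by camera, adjusted p = 0.264 with an estimated correlation). CDC20, an activator of the anaphase ubiquitin ligase, changed by -2.48 ± 0.26, the mitotic kinase AURKB by -1.87 ± 0.16, the nucleotide enzyme TK1 by -1.94 ± 0.21 and the kinetochore protein CENPF by -1.75 ± 0.19. LMNB1, a nuclear lamin on the senescence list, fell by 1.89 ± 0.29, and IGFBP5, a growth factor binding protein on that list, rose by 1.49 ± 0.14. Of the 14 senescence-associated genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone). The list passed camera (adjusted p = 0.0119, adjusted p = 0.202 with an estimated correlation) but not after median-of-ratios scaling (adjusted p = 0.203) or quantile normalization (adjusted p = 0.317).

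Of the 14 contractile and smooth muscle genes, 11 rose and none fell (11 adjusted over the list alone), with a median of 0.68, or 0.87 relative to all genes (adjusted p = 6.5e-18 by camera, adjusted p = 0.0105 with an estimated correlation). ACTA2, smooth muscle actin, went from 703 ± 126 to 2160 ± 316 RPKM, CNN1, calponin, rose by 1.39 ± 0.11, LMOD1 by 1.37 ± 0.12 and ACTG2 by 1.52 ± 0.16. Among 21 targets and members of TGF-beta and BMP signalling, which drives contractile and matrix genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 8.8e-07, adjusted p = 0.00877 with an estimated correlation). INHBA, an activin subunit, rose by 1.18 ± 0.15, TGFB2 by 1.24 ± 0.16 and ID3 by 0.79 ± 0.14, while the latent TGF-beta binding protein LTBP2 fell by 0.67 ± 0.10. YAP and TEAD targets, read out in response to stretch and stiffness, had 7 of 15 rise and 3 fall (7 and 3 adjusted over the list alone; camera adjusted p = 4.8e-04, adjusted p = 0.142 with an estimated correlation). Of 23 integrin and adhesion genes 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.00132, adjusted p = 0.0379 with an estimated correlation). Of these genes 10 rose and 3 fell after median-of-ratios scaling, and 8 and 3 after quantile normalization (adjusted p = 0.0836). ITGA7, a laminin receptor of muscle, rose by 0.89 ± 0.09, and ITGA10, a collagen receptor of cartilage, fell by 1.52 ± 0.24.

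No lineage list passed camera with Ag. Of 12 osteogenic genes 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.262), a count of 3 after median-of-ratios scaling. ALPL, the alkaline phosphatase of mineralizing cells, fell by 1.08 ± 0.21, and RUNX2, the transcription factor of bone formation (Entrez gene 860, chromosome 6, 45328330 to 45551082), fell by 0.57 ± 0.14. Of 8 chondrogenic genes 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.914): COL10A1, the collagen of hypertrophic cartilage, fell by 1.53 ± 0.31 and the secreted protein CYTL1 fell by 1.22 ± 0.18. CYTL1 went from 82 to 18 reads, 5.38 times lower after library totals (95% interval 3.20 to 9.52). Among 12 adipogenic genes 2 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.191), which turned to 3 rising and 2 falling under both other scalings. The fatty acid receptor CD36 rose by 0.99 ± 0.19 and the lipolysis inhibitor G0S2 fell by 2.16 ± 0.36. Of 14 mesenchymal stem cell markers 3 rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.645). MCAM rose by 1.32 ± 0.13 and LEPR, the leptin receptor, by 0.99 ± 0.12, while PDGFRA and NT5E changed by -0.83 ± 0.09 and -0.63 ± 0.08. Too few members for a list test were present for skeletal and cardiac muscle (2 of 4 rose) and the neural lineage (1 of 3 rose and 1 fell).

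Counts of metal and stress genes depended on scaling. Of 9 metallothionein and zinc genes 2 rose and 2 fell (3 and 2 adjusted over the list alone), or 4 and 1 under both other scalings. MT1F rose by 1.07 ± 0.18, from 2 to 29 reads (ratio 12.3, 95% interval 3.11 to 106), and MT1E fell from 119 ± 8.30 to 56.7 ± 14.8 RPKM; paralogs of this family share sequence, so reads can be split between them unevenly. MT2A fell by 0.78 ± 0.24 (adjusted p = 0.0198), a call lost after median-of-ratios scaling (adjusted p = 0.112), quantile normalization (adjusted p = 0.0512), and without control 1 (adjusted p = 0.254), Ag 1 (adjusted p = 0.0690) or Ag 3 (adjusted p = 0.0587). The list's median was -0.08, its mean 0.40 and camera pointed up (adjusted p = 0.0283, adjusted p = 0.481 with an estimated correlation), a call lost after median-of-ratios scaling, where the median was 0.09 (adjusted p = 0.203), and without Ag 2 (adjusted p = 0.0936). Copper handling had 1 of 12 rise and 3 fall (1 and 3 adjusted over the list alone), with the copper exporter ATP7B higher by 0.45 ± 0.11. Iron handling had 1 of 9 fall (0 adjusted over the list alone), which became 1 rising under both other scalings. Of 20 NRF2 and antioxidant genes 2 rose and 5 fell, or 3 and 3 after median-of-ratios scaling. HMOX1, heme oxygenase, fell by 1.44 ± 0.32, and the glutathione peroxidases GPX1 and GPX4 changed by -0.86 ± 0.15 and -0.73 ± 0.15. Heat shock and chaperone genes rose in 4 and fell in 6 of 15 cases (6 and 2 after median-of-ratios scaling, 6 and 3 after quantile normalization), with the small heat shock protein HSPB1 higher by 0.69 ± 0.11. ER stress and amino acid response genes rose in 3 and fell in 8 of 20, and p53 targets rose in 1 and fell in 6 of 16 (2 and 3 under both other scalings). None of these 6 lists passed camera (adjusted p = 0.914, 0.834, 0.914, 0.146, 0.750 and 0.909 for copper, iron, NRF2, heat shock, ER stress and p53). Adjusted over the list alone, the counts of the last 4 were 2 and 5, 4 and 6, 3 and 8, and 1 and 6.

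Of 21 glycolysis genes 16 rose and none fell (17 and 1 adjusted over the list alone; median 0.66, or 0.85 relative to all genes; camera adjusted p = 4.8e-13, adjusted p = 0.202 with an estimated correlation). GAPDH went from 3294 ± 145 to 4907 ± 459 RPKM and ALDOA rose by 0.66 ± 0.12. Hypoxia and angiogenic genes rose in 9 and fell in 2 of 18 (10 and 2 adjusted over the list alone; camera adjusted p = 4.0e-08, adjusted p = 0.140 with an estimated correlation), with 12 rising after median-of-ratios scaling. ANGPT1, a vessel-stabilizing factor, rose by 0.97 ± 0.13, the peptide hormone ADM by 0.98 ± 0.17 and STC2 by 1.11 ± 0.21. HGF, hepatocyte growth factor, fell by 1.20 ± 0.20. For both lists Ti a lay within the range of the Ag libraries and Ti b did not. Library medians for glycolysis were 0.54, 0.78 and 0.57 with Ag, 0.57 in Ti a and -0.09 in Ti b. Those for hypoxia and angiogenic genes were 0.71, 0.96 and 0.49 with Ag, 0.71 in Ti a and -0.18 in Ti b. Interferon response genes had a median of 1.04, with 3 of 20 rising (1 adjusted over the list alone; camera adjusted p = 6.7e-09, adjusted p = 0.481 with an estimated correlation), and library medians of 1.09, 1.85 and 0.12. For this list Ti a lay higher than the Ag libraries, at 2.32, and Ti b at -0.49. Inflammatory and NF-kB genes rose in 2 of 22 (1 adjusted over the list alone; camera adjusted p = 7.7e-04, adjusted p = 0.703 with an estimated correlation, adjusted p = 0.293 after median-of-ratios scaling, and adjusted p = 0.755 without control 2). The controls differed on the inflammatory list, with medians of 0.91 in control 1 and -0.91 in control 2, and the Ag libraries lay between them at 0.04, 0.32 and 0.56. Of 35 ribosomal protein genes 29 fell (32 adjusted over the list alone; median -0.39, or -0.20 relative to all genes; camera adjusted p = 6.6e-05, adjusted p = 0.703 with an estimated correlation), or 10 after median-of-ratios scaling and 23 after quantile normalization. RPL3 fell by 0.63 ± 0.10 and RPL10 fell by 0.53 ± 0.10.

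The other fixed lists did not pass camera with Ag. Matrix glycoproteins rose in 7 and fell in 7 of 25 (adjusted p = 0.0521), or in 10 and 4 after median-of-ratios scaling and 5 and 6 after quantile normalization. Matrix proteases did so in 4 and 4 of 18 (adjusted p = 0.284) and collagens in 2 and 3 of 17 (adjusted p = 0.226, with 4 and 2 after median-of-ratios scaling). Wnt targets and inhibitors rose in 3 and fell in 5 of 12 (adjusted p = 0.989): the ligand WNT5A rose by 1.01 ± 0.13, and the Wnt inhibitor SFRP4 and the Wnt-induced WISP1 changed by -1.58 ± 0.24 and -1.78 ± 0.27. Immediate early and MAPK targets rose in 2 and fell in 9 of 19 (adjusted p = 0.914), cholesterol synthesis genes in 2 and 1 of 20 (adjusted p = 0.0521), and none of 7 histone genes passed (adjusted p = 0.395). Lysosome and autophagy genes fell in 8 of 23 and rose in none (adjusted p = 0.515), which turned to 4 rising and 2 falling after median-of-ratios scaling and 5 falling after quantile normalization. Nuclear-encoded oxidative phosphorylation genes fell in 9 of 24 (adjusted p = 0.126), or in 2 after median-of-ratios scaling and 5 after quantile normalization. Adjusted over the list alone, these counts were the same except for 3 and 6 Wnt genes, 3 and 9 MAPK genes, and 0 and 1 cholesterol genes. Markers of other cell types were few in the table: 1 of 2 endothelial markers rose and 1 fell, 2 of 3 blood and immune markers fell, with a change of -1.13 ± 0.14 for CD14, and 1 of 4 epithelial markers fell. For the copper, iron, NRF2, heat shock, adipogenic, stem cell marker, collagen, glycoprotein, protease, Wnt and histone lists the median change was below 0 while camera, which compares a list with all other genes, pointed up.

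By limma's moderated test 4229 of 11320 genes passed for Ag, 725 higher and 3504 lower. The median gene shifted by -0.19 with Ag and by -0.11 with Cu, so changes near these sizes depend on scaling. After median-of-ratios scaling, which sets this median near 0, 3284 genes passed, 1657 higher and 1627 lower, of which 2352 were among the 4229; quantile normalization gave 1665 higher and 1827 lower. Without control 1 the count was 1955, without control 2 it was 1919 and without Ag 1 it was 2537. STC1, a secreted glycoprotein hormone that rose from 4.19 ± 3.56 to 30.7 ± 3.53 RPKM, lost its call without control 2 (adjusted p = 0.0578).

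**Figure D2:**
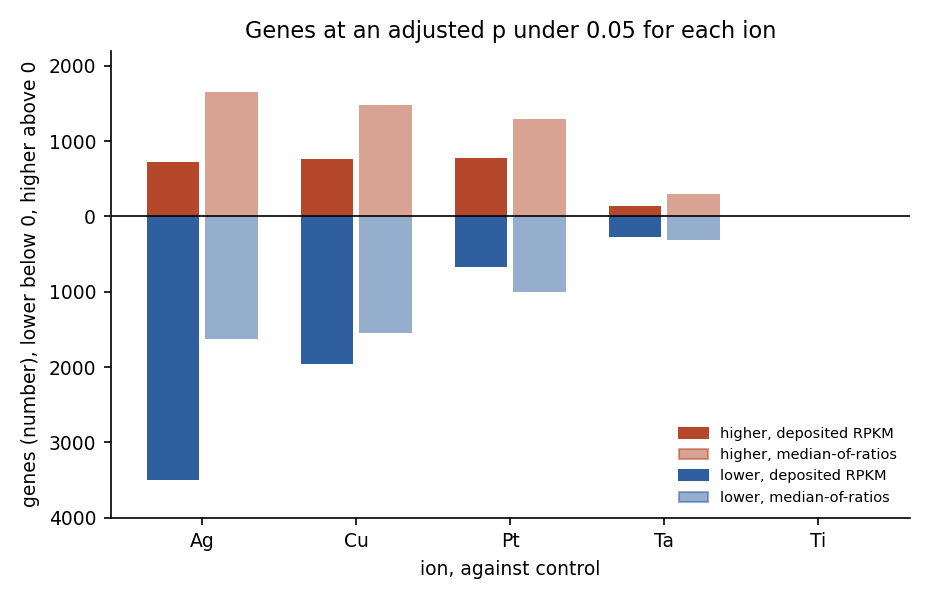
Number of genes past an adjusted p of 0.05 for each ion against control, higher above 0 and lower below 0, with RPKM as deposited (dark bars) and after median-of-ratios scaling (light bars). With Ag 725 genes were higher and 3504 lower as deposited, against 1657 and 1627 after scaling.

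The same question was asked for Cu, and the largest changes included genes of muscle, secreted and membrane proteins. TM4SF20 rose from 8.74 ± 0.657 in control (n = 2) to 124 ± 14.0 RPKM with Cu (SD, n = 3; adjusted p = 2.9e-08). CRYAB, a small heat shock protein (Entrez gene 1410, chromosome 11, 111908564 to 111923740), rose from 97.2 ± 7.99 to 491 ± 42.9 RPKM (adjusted p = 6.3e-09). ACTC1, cardiac actin (Entrez gene 70, chromosome 15, 34790230 to 34795549), rose from 0.613 ± 0.329 to 15.1 ± 3.82 RPKM. INHBB, an activin subunit, rose by 2.91 ± 0.38, the protease inhibitor SLPI by 2.25 ± 0.29, LEP by 2.18 ± 0.29 (read ratio 20.9, 95% interval 10.8 to 46.3) and the adhesion molecule MCAM by 1.99 ± 0.13. COLEC12, a scavenger receptor (Entrez gene 81035, chromosome 18, 316737 to 500701), fell from 18.0 ± 1.70 to 0.389 ± 0.0640 RPKM, and CHI3L1, a secreted chitinase-like protein (Entrez gene 1116, chromosome 1, 203178931 to 203186704), from 127 ± 9.62 to 9.24 ± 0.683 RPKM. CXCL12 changed by -3.62 ± 0.45, the bone-resorbing protease CTSK by -2.86 ± 0.56, the joint growth factor GDF5 by -2.83 ± 0.22 and the matrix protein AEBP1 by -2.76 ± 0.28.

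Contractile genes rose in 13 of 14 cases with Cu (13 adjusted over the list alone; median 0.60, or 0.71 relative to all genes; camera adjusted p = 3.8e-18, adjusted p = 0.0101 with an estimated correlation). CNN1 went from 48.6 ± 5.31 to 193 ± 26.4 RPKM, ACTA2 rose by 1.43 ± 0.15 and ACTG2 by 1.70 ± 0.16. Of 4 skeletal and cardiac muscle genes 3 rose, ACTC1 with MYH3, an embryonic myosin, by 1.82 ± 0.20 and DES, the muscle filament desmin, by 0.63 ± 0.11. TGF-beta and BMP genes rose in 10 and fell in 2 of 21 (13 and 3 adjusted over the list alone; camera adjusted p = 2.7e-07, adjusted p = 0.00595 with an estimated correlation). The BMP-induced ID3 went from 121 ± 4.39 to 354 ± 24.4 RPKM, ID2 rose by 1.70 ± 0.17 and CTGF by 1.19 ± 0.15. YAP and TEAD targets rose in 7 and fell in 2 of 15 (7 and 3 adjusted over the list alone; camera adjusted p = 0.00534, adjusted p = 0.374 with an estimated correlation). That call was lost after median-of-ratios scaling (adjusted p = 0.0529) and quantile normalization (adjusted p = 0.0702). Wnt targets and inhibitors rose in 1 and fell in 7 of 12 (1 and 8 adjusted over the list alone; camera adjusted p = 0.117, and 0.0428 after median-of-ratios scaling). Changes were -2.20 ± 0.27 for WISP1, -1.84 ± 0.24 for SFRP4 and 0.71 ± 0.13 for WNT5A.

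Lineage genes divided. Of 12 osteogenic genes 5 fell and none rose (5 adjusted over the list alone; camera adjusted p = 0.243): POSTN, the matrix protein periostin, fell from 3666 ± 135 to 1289 ± 78.1 RPKM, ALPL fell by 0.98 ± 0.21 and RUNX2 fell by 0.63 ± 0.14. Of 8 chondrogenic genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.243), with a median of 0.15 and a mean of -0.03. COL11A1, a cartilage collagen, rose by 1.15 ± 0.20 and ACAN, the cartilage proteoglycan aggrecan, rose as well, while COL10A1 fell by 2.38 ± 0.31 and CYTL1 fell by 1.51 ± 0.18. CYTL1 went from 82 to 8 reads, 12.5 times lower after library totals (95% interval 6.04 to 29.9). Adipogenic genes rose in 1 and fell in 3 of 12 (1 and 3 adjusted over the list alone; camera adjusted p = 0.970), with the fatty acid desaturase SCD lower at 20.2 ± 5.37 against 61.3 ± 3.05 RPKM. Matrix genes went both ways: 7 of 25 glycoproteins rose and 6 fell and 5 of 17 collagens rose and 5 fell. TNC, FBLN1 and the fibrillar COL3A1 changed by -1.69 ± 0.10, -1.41 ± 0.14 and -0.83 ± 0.10, while the basement membrane COL4A1 rose by 0.78 ± 0.15.

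Of 9 metallothionein and zinc genes 1 rose and 3 fell with Cu (1 and 4 adjusted over the list alone; camera adjusted p = 0.499). MT2A fell from 1157 ± 392 to 275 ± 14.5 RPKM, MT1E fell by 1.75 ± 0.21, and MT1M went from 26 to 2 reads (15.8 times lower, 95% interval 3.96 to 138). Of 12 copper handling genes 1 rose, ATP7B by 0.47 ± 0.11, and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.970), with a median of -0.07 that became 0.05 after median-of-ratios scaling. Iron handling genes rose in 1 and fell in 2 of 9 (1 and 3 adjusted over the list alone; camera adjusted p = 0.946), or in 3 and 1 under both other scalings. FTH1, the ferritin heavy chain, went from 5231 ± 838 to 2650 ± 141 RPKM. Among 20 NRF2 and antioxidant genes 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.0971), or 9 and 3 under both other scalings. SRXN1 rose by 0.65 ± 0.09, the cystine transporter SLC7A11 by 0.70 ± 0.16, and HMOX1 fell by 2.41 ± 0.32. Heat shock genes rose in 5 and fell in 1 of 15 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00151, adjusted p = 0.590 with an estimated correlation), with HSPB1 higher by 0.99 ± 0.11 and HSPB8 by 0.94 ± 0.12. For the NRF2 list the median was 0.08 and the mean -0.16, and for the iron and adipogenic lists the medians lay below 0 while camera pointed up.

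Proliferation genes fell in 23 of 25 cases with Cu (24 adjusted over the list alone; median -1.27, or -1.16 relative to all genes; camera adjusted p = 1.5e-11, adjusted p = 0.590 with an estimated correlation). TK1 fell by 1.65 ± 0.21, AURKB fell by 1.27 ± 0.16 and BUB1B fell by 1.26 ± 0.17. Ribosomal protein genes fell in 31 of 35 (35 adjusted over the list alone; median -0.51, or -0.40 relative to all genes; camera adjusted p = 1.7e-11, adjusted p = 0.590 with an estimated correlation), or in 28 after quantile normalization. Interferon response genes fell in 10 of 20 (17 adjusted over the list alone; median -1.64; camera adjusted p = 0.00478, adjusted p = 0.793 with an estimated correlation), or 4 under both other scalings. IRF9, a subunit of the interferon-activated transcription complex, fell by 1.12 ± 0.25, a call lost without control 1 (adjusted p = 0.0568). Glycolysis genes rose in 5 of 21 (9 adjusted over the list alone; camera adjusted p = 1.3e-06, adjusted p = 0.590 with an estimated correlation), or in 6 after median-of-ratios scaling and 10 after quantile normalization. Lysosome and autophagy genes fell in 10 of 23 (10 adjusted over the list alone; camera adjusted p = 0.122), with the protease CTSB lower at 948 ± 4.58 against 2417 ± 293 RPKM and the autophagy receptor SQSTM1 at 259 ± 12.3 against 576 ± 85.6 RPKM. The sterol sensor INSIG1 fell by 1.75 ± 0.17. All 3 blood and immune markers fell, with CD68 at 34.4 ± 1.11 against 75.2 ± 0.359 RPKM.

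By limma's moderated test 2725 genes passed for Cu, 768 higher and 1957 lower. After median-of-ratios scaling 3030 passed, 1479 higher and 1551 lower, 2313 of them among the 2725. Without control 1 the count was 1258 and without control 2 it was 1687.

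With Pt, at the lowest dose of the 5 ions, the comparison with control showed epithelial-type keratins and contractile genes higher and division genes lower. TM4SF20 stood at 48.6 ± 10.7 RPKM (SD, n = 2) against 8.74 ± 0.657 (n = 2), an increase of 2.33 ± 0.20 (adjusted p = 5.6e-05). PPP1R14A, an inhibitor of myosin phosphatase, rose by 1.61 ± 0.28, the tubulin-binding TPPP3 by 1.56 ± 0.25 and the protease inhibitor SERPINB7 by 1.30 ± 0.15. The keratins KRT7, KRT18 and KRT19 rose by 1.38 ± 0.25, 1.27 ± 0.18 and 1.02 ± 0.15, and 3 of 4 epithelial markers rose. CHI3L1 fell from 127 ± 9.62 to 10.3 ± 2.51 RPKM, CXCL12 from 46.9 ± 6.87 to 4.08 ± 0.706 RPKM and COLEC12 from 18.0 ± 1.70 to 1.28 ± 0.266 RPKM, while AEBP1 fell by 2.31 ± 0.31.

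Of 25 proliferation genes 19 fell with Pt (23 adjusted over the list alone, 22 after median-of-ratios scaling; median -1.10; camera adjusted p = 1.3e-17, adjusted p = 0.424 with an estimated correlation). Changes were -2.03 ± 0.34 for the ubiquitin-conjugating UBE2C, -1.60 ± 0.21 for the kinase PLK1, -1.56 ± 0.18 for AURKB and -1.49 ± 0.23 for the division marker MKI67. Contractile genes rose in 9 of 14 (10 adjusted over the list alone; camera adjusted p = 1.2e-08, adjusted p = 0.225 with an estimated correlation), or in 6 after quantile normalization. CNN1 rose by 1.23 ± 0.12, ACTG2 by 1.22 ± 0.17 and TAGLN, transgelin, from 6052 ± 88.7 to 9451 ± 228 RPKM. Matrix glycoproteins rose in 1 and fell in 6 of 25 (1 and 7 adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.390 with an estimated correlation), with 10 falling after quantile normalization. TNC changed by -1.16 ± 0.11 and FBLN1 by -1.23 ± 0.16, and the collagen COL6A3 was at 291 ± 8.18 against 654 ± 7.69 RPKM. That list lost its call without control 2 (adjusted p = 0.0567), Pt a (0.0583), Ti a (0.0962) or Ti b (0.0965). Nuclear-encoded oxidative phosphorylation genes rose in 5 of 24 (11 adjusted over the list alone; median 0.31; camera adjusted p = 5.4e-05, adjusted p = 0.709 with an estimated correlation), such as NDUFA4 by 0.70 ± 0.13. Of this list 12 rose after median-of-ratios scaling, while 3 rose and 1 fell after quantile normalization (median 0.14). The call of NDUFA4, not of the list, was lost without control 2 (adjusted p = 0.0589) or Pt a (adjusted p = 0.0614). Histone genes rose in 3 of 7 (5 adjusted over the list alone; camera adjusted p = 0.00182, adjusted p = 0.643 with an estimated correlation), with HIST1H1C at 82.1 ± 3.99 against 40.8 ± 4.36 RPKM.

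No lineage list passed camera with Pt. Osteogenic genes fell in 2 of 12 (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.377). POSTN fell by 0.66 ± 0.11 and RUNX2 fell by 0.64 ± 0.15. The RUNX2 call was lost without control 1 (adjusted p = 0.0675), control 2 (0.0828), Pt a (0.0625) or Pt b (0.0913). Chondrogenic genes rose in 2 and fell in 2 of 8 (2 and 2 adjusted over the list alone; camera adjusted p = 0.948; median 0.15, mean -0.10). The matrix linker HAPLN1 was higher by 0.53 ± 0.10 and CYTL1 at 0.573 ± 0.244 against 2.39 ± 0.328 RPKM. CYTL1 went from 82 to 15 reads, 4.13 times lower after library totals (95% interval 2.37 to 7.72). Adipogenic genes rose in 1 and fell in 2 of 12 (1 and 4 adjusted over the list alone; camera adjusted p = 0.212). None of the 9 metallothionein and zinc genes passed (0 adjusted over the list alone; camera adjusted p = 0.573). Of 12 copper handling genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.132). MCAM rose by 0.93 ± 0.14 and PDGFRA fell by 0.58 ± 0.10.

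Further lists passed camera with Pt on few or no single genes. Interferon response genes had a median of -1.18 with none of 20 passing (adjusted p = 0.00159, adjusted p = 0.709 with an estimated correlation). Inflammatory genes had a median of -0.98 with 1 of 22 rising (adjusted p = 0.00936, adjusted p = 0.711 with an estimated correlation, and adjusted p = 0.886 without control 1). The inflammatory list had library medians of 0.91 in control 1 and -0.91 in control 2, against -0.97 and -1.05 with Pt, so the Pt libraries lay near control 2. Heat shock genes rose in 5 of 15 (adjusted p = 0.0174, adjusted p = 0.709 with an estimated correlation, and 0.237 after quantile normalization), with CRYAB higher by 0.81 ± 0.11. ER stress and amino acid genes rose in 4 of 20 (adjusted p = 0.0312, adjusted p = 0.709 with an estimated correlation), with the serine synthesis enzyme PSAT1 higher by 0.56 ± 0.10. This call was lost under median-of-ratios scaling (0.0627) and quantile normalization (0.981), and without control 2 (0.0567) or Pt b (0.201). TGF-beta and BMP genes rose in 4 and fell in 1 of 21 (adjusted p = 0.0494, adjusted p = 0.390 with an estimated correlation), with ID3 higher by 1.00 ± 0.15. This too was lost under median-of-ratios scaling (0.101), quantile normalization (0.0914) and without any of control 1 (0.0592), control 2 (0.0567), Cu 3 (0.0534), Pt a (0.0503), Pt b (0.0824), Ta 1 (0.0566) or Ta 2 (0.0559). Lysosome and autophagy genes rose in 1 and fell in 5 of 23 (adjusted p = 0.0298, adjusted p = 0.709 with an estimated correlation), lost without control 2 (0.0516) or Pt b (0.0790). In this list 7 fell after median-of-ratios scaling and 11 after quantile normalization. Ribosomal protein genes had a median of 0.13 with none passing (adjusted p = 0.0190, adjusted p = 0.759 with an estimated correlation, lost without control 2 at 0.182 or Pt a at 0.106), and the direction turned after quantile normalization (median -0.07, adjusted p = 0.0335). There 3 of these genes fell, while 7 rose after median-of-ratios scaling. Adjusted over the list alone, these 7 lists gave 0, 1, 5, 4, 5 and 1, 1 and 6, and 0 genes.

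By limma's moderated test 1436 genes passed for Pt, 771 higher and 665 lower; with 2 libraries against 2 the error rests on the spread of all 15 libraries. Without control 1 the count was 667, without control 2 it was 445, without Pt a 425, without Pt b 524, without Ti a 2394 and without Ti b 2393, and after median-of-ratios scaling it was 2298.

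The Ta comparison gave fewer genes past the threshold than those of Ag, Cu and Pt. CRIP1, a cysteine-rich LIM protein (Entrez gene 1396, chromosome 14, 105486886 to 105488947), rose from 111 ± 0.228 (n = 2) to 238 ± 4.64 RPKM (SD, n = 3; adjusted p = 7.1e-04). WISP2, a secreted matricellular protein (Entrez gene 8839, chromosome 20, 44714861 to 44727811), fell from 48.1 ± 6.51 to 10.1 ± 0.415 RPKM (adjusted p = 6.8e-04). TPPP3 rose by 1.41 ± 0.22, TM4SF20 by 1.31 ± 0.19, ACTC1 by 1.19 ± 0.19, the elastic fibre protein ELN by 1.18 ± 0.30 and KRT7 by 1.14 ± 0.23. CHI3L1 changed by -2.81 ± 0.49, COLEC12 by -2.18 ± 0.38, CXCL12 by -2.16 ± 0.45 and CTSK by -2.14 ± 0.56. By limma's moderated test ELN (adjusted p = 0.0434) and CTSK (adjusted p = 0.0475) lay near the threshold. Both calls were lost without any 1 of the Ag or Cu libraries. That of ELN was also lost after median-of-ratios scaling (adjusted p = 0.0545) and quantile normalization (adjusted p = 0.0522). Contractile genes rose in 4 of 14 (11 adjusted over the list alone; median 0.25; camera adjusted p = 4.4e-12, adjusted p = 0.0384 with an estimated correlation). CNN1 rose by 0.72 ± 0.11, ACTG2 by 0.89 ± 0.16, TPM2 by 0.62 ± 0.11 and ACTA2 by 0.64 ± 0.15. TGF-beta and BMP genes rose in 3 of 21 (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.0146 with an estimated correlation), among them ID3 by 0.76 ± 0.14 and the pseudoreceptor BAMBI by 0.46 ± 0.11.

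Stress and lipid genes followed with Ta. Of 20 ER stress and amino acid genes 2 rose (5 adjusted over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.505 with an estimated correlation): CHAC1, a glutathione-degrading enzyme, by 0.69 ± 0.11 and PSAT1 by 0.37 ± 0.09. Heat shock genes rose in 2 of 15 (3 adjusted over the list alone; camera adjusted p = 5.7e-04, adjusted p = 0.505 with an estimated correlation), CRYAB by 0.70 ± 0.10 and HSPB1 by 0.50 ± 0.11. Cholesterol synthesis genes had a median of -0.24, with 1 of 20 falling (7 falling adjusted over the list alone; camera adjusted p = 2.0e-04, adjusted p = 0.594 with an estimated correlation): INSIG1, at 19.4 ± 0.797 against 47.1 ± 3.93 RPKM. Lysosome genes fell in 3 of 23 (1 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.710 with an estimated correlation), a call lost without control 2 (0.0637) or Ta 1 (0.0829). They rose in 1 and fell in 5 after median-of-ratios scaling, and in 1 and 6 after quantile normalization. Ribosomal protein genes had a median of -0.21 (camera adjusted p = 1.7e-05, adjusted p = 0.705 with an estimated correlation). Interferon genes had a median of -0.93 relative to all genes (camera adjusted p = 0.0101, adjusted p = 0.746 with an estimated correlation, and 0.0829 without Ta 1), and in neither list did a member pass (0 adjusted over the list alone). Ribosomal protein genes fell in 2 cases after median-of-ratios scaling and 8 after quantile normalization. None of the 25 proliferation genes passed with Ta (0 adjusted over the list alone; median -0.27, camera adjusted p = 0.0511, and 0.00817 after median-of-ratios scaling). Osteogenic genes fell in 2 of 12, with -0.64 ± 0.10 for POSTN and -0.61 ± 0.14 for RUNX2. Chondrogenic genes fell in 2 of 8, CYTL1 with -0.85 ± 0.18 and COL10A1 (list median 0.24, mean -0.03), and adipogenic genes in 1 of 12, with -1.34 ± 0.25 for SCD. Adjusted over the list alone these were 2, 1 rising and 2 falling, and 2 rising and 4 falling, and none of the 3 lists passed camera (adjusted p = 0.929, 0.263 and 0.986). A further 5 lists passed camera and pointed up with Ta on 0 to 2 members each. They included YAP and TEAD targets (adjusted p = 4.6e-04, adjusted p = 0.220 with an estimated correlation), collagens (adjusted p = 0.00119, adjusted p = 0.592 with an estimated correlation) and histones (adjusted p = 0.00119, adjusted p = 0.505 with an estimated correlation). The others were MAPK targets (adjusted p = 0.00953, adjusted p = 0.220 with an estimated correlation) and glycolysis (adjusted p = 7.2e-05, adjusted p = 0.594 with an estimated correlation). Adjusted over the list alone, 4 YAP and TEAD targets rose, 4 collagens rose and 1 fell, and 0 histones, 1 MAPK target and 1 glycolysis gene rose. The collagen call was lost without control 1 (0.136) and after quantile normalization (0.0769), and the MAPK and glycolysis calls without control 2 (0.161 and 0.370).

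By limma's moderated test 414 genes passed for Ta, 141 higher and 273 lower, or 298 and 313 after median-of-ratios scaling. Without control 1, 5 genes passed, all among the 414, and 25 of the 27 genes named for Ta lost their call, with CRIP1 and WISP2 as the exceptions. The changes themselves kept much of their size without control 1, at 1.47 against 1.41 for TPPP3, -2.89 against -2.81 for CHI3L1, -2.27 against -2.18 for COLEC12 and 0.46 against 0.64 for ACTA2, the largest loss as a proportion. Of these 27 genes, 13 lost it without control 2, 9 without Ta 1, 11 without Ta 2 and 8 without Ta 3, and 2 to 5 without any 1 of the Ag, Cu or Pt libraries. The count was 128 without control 2, 131 without Ta 1, 133 without Ta 2, 230 without Ta 3, 1107 without Ti a and 1108 without Ti b.

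For Ti against control, the same question found no single gene past the threshold. By limma's moderated test 0 of 11320 genes passed, with 944 at an unadjusted p under 0.05, and limma's voom with weights from recovered reads gave 0. The comparison rested on 2 libraries against 2, and the Ti libraries differed from each other more than replicates of any other group. The spread shared by all 6 groups lay below that of Ti (SD 0.304, against 0.119 to 0.154 in the other groups), so p-values for Ti tend to be too small. The smallest p-values were those of ID3, with a change of 0.92 ± 0.15 (230 ± 28.5 against 121 ± 4.39 RPKM, SD, n = 2 each), and IL11, a cytokine downstream of TGF-beta, with 1.12 ± 0.19 (adjusted p = 0.148 for both). Next came FSTL3, an activin inhibitor, with 0.92 ± 0.18, and the heparan sulfatase SULF1, with -0.75 ± 0.16 (adjusted p = 0.395 for both). TGF-beta and BMP genes had a median of 0.37 (0 of 21 passed, 5 higher adjusted over the list alone; camera adjusted p = 4.6e-11, adjusted p = 8.8e-04 with an estimated correlation). ATOH8 changed by 0.87 ± 0.19 and CTGF by 0.55 ± 0.17. This list kept its direction and call in every fit that left out 1 library. Without Ti b, 1871 genes passed, 326 higher and 1545 lower, and without Ag 3 the count was 1.

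Interferon response genes had a median of 2.32 in Ti a and -0.49 in Ti b against the control mean (camera adjusted p = 3.3e-07 and up, adjusted p = 0.754 with an estimated correlation; 9.8e-09 and down without Ti a). Proliferation genes had medians of -0.86 and -0.02 (camera adjusted p = 4.5e-08, adjusted p = 0.754 with an estimated correlation), and contractile genes medians of 0.18 and 0.21 (camera adjusted p = 2.1e-06, adjusted p = 0.140 with an estimated correlation). Glycolysis genes (adjusted p = 1.6e-04, adjusted p = 0.754 with an estimated correlation) lost their call without control 2 (0.635) and turned down without Ti a (4.2e-05). YAP and TEAD targets (adjusted p = 0.00128, adjusted p = 0.189 with an estimated correlation) pointed down and lost their call without Ti a (0.726). Ribosomal protein genes (adjusted p = 1.6e-04, adjusted p = 0.806 with an estimated correlation) had a median of 0.09 that became -0.02 after quantile normalization (0.548), and their call was lost without control 2 (0.102) or Ti b (0.363). Immediate early and MAPK targets (adjusted p = 0.00396, adjusted p = 0.140 with an estimated correlation) lost their call without control 2 (0.126) or Ti a (0.164). Senescence-associated genes (adjusted p = 8.3e-04, adjusted p = 0.140 with an estimated correlation) lost it without Ti a (0.755), and heat shock genes (adjusted p = 0.0142, adjusted p = 0.754 with an estimated correlation) without control 1 (0.0904) or Ti b (0.575). After quantile normalization camera no longer called glycolysis (adjusted p = 0.0788), YAP and TEAD targets (0.0574), senescence-associated genes (0.0565) or heat shock genes (0.164). Adjusted over the list alone, 2 MAPK targets and 1 heat shock gene passed and none of the other lists named here had a member that did.

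**Figure D3:**
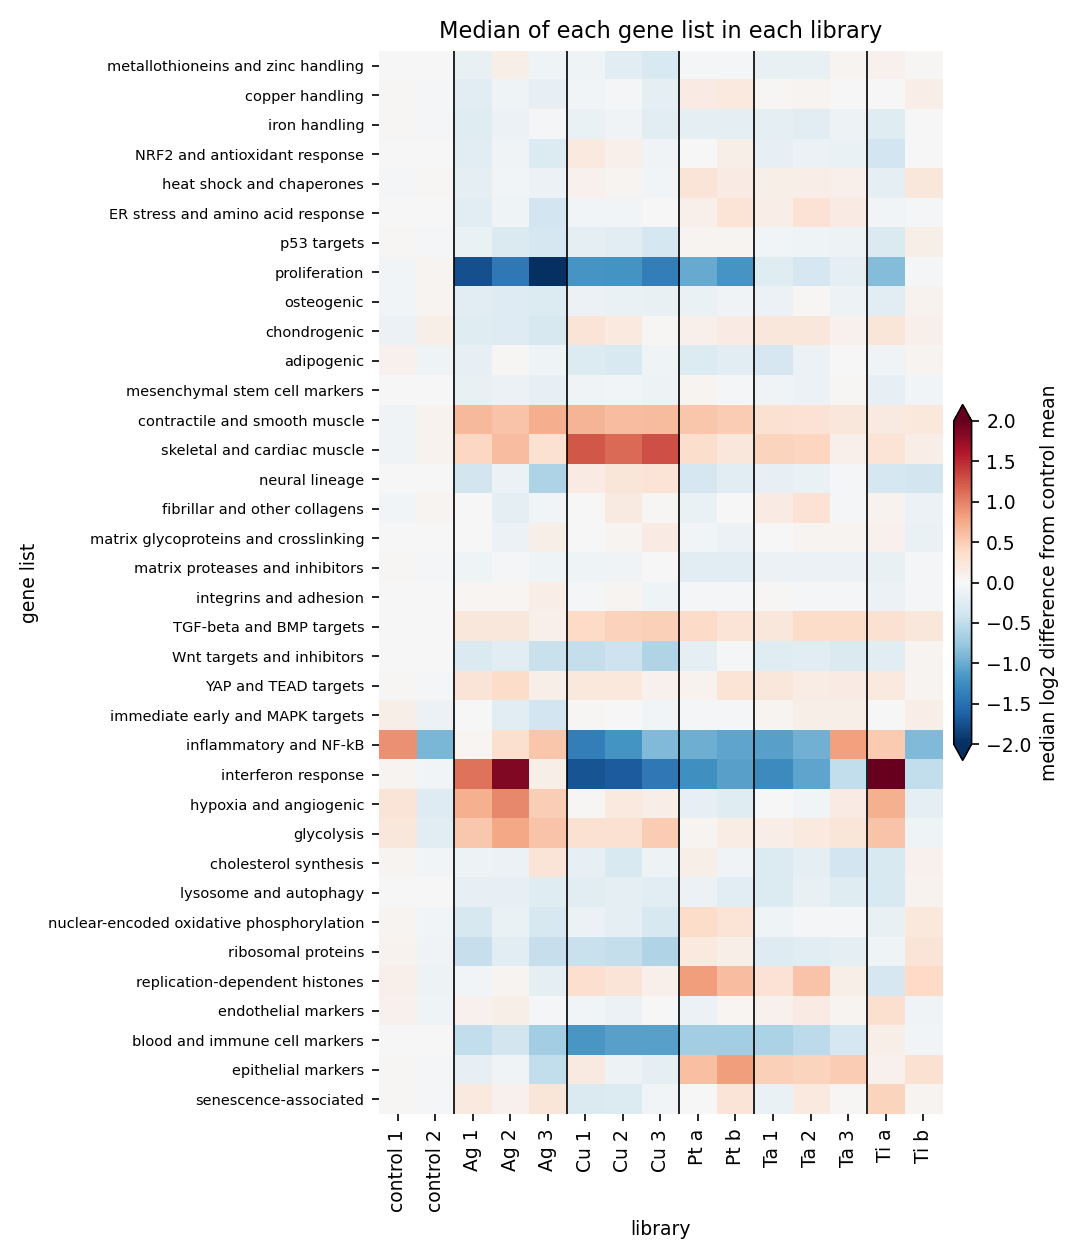
Median difference from the control mean, in log2 units, of each of 36 gene lists (rows) in each of the 15 libraries (columns), red higher and blue lower. Proliferation genes lie at -1.76, -1.43 and -2.04 in the Ag libraries, and interferon response genes at 2.32 in Ti a and -0.49 in Ti b.

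Direct comparisons between ions asked which effects differed at these doses. MT1G had 466 reads with Ag, 9 with Cu, 3 with Pt, 5 with Ta and 2 with Ti. After library totals it was lower than with Ag by 53.4 times with Cu (95% interval 27.9 to 118), 99.5 times with Pt (33.9 to 484), 110 times with Ta (46.8 to 340) and 170 times with Ti (46.8 to 1410). TXNIP was higher than with Ag by 4.77 ± 0.73 with Cu, 4.67 ± 0.81 with Pt and 4.62 ± 0.73 with Ta, and its relative ARRDC4, another arrestin-domain protein controlled by glucose, by 2.66 ± 0.47 with Cu and 3.03 ± 0.52 with Pt. CRIP1 stood at 22.4 ± 3.42 RPKM with Ag (n = 3), against 220 ± 15.6 with Pt (n = 2), 238 ± 4.64 with Ta (n = 3) and 162 ± 5.83 with Ti (n = 2). KRT14 was higher than with Ag by 2.74 ± 0.20 with Ta and 2.31 ± 0.22 with Ti. The interferon-induced IFI6 differed from Ag by -4.75 ± 0.73 with Cu and by -3.39 ± 0.73 with Ta. As a list, interferon genes were lower than with Ag for Cu (median -2.59, camera adjusted p = 1.2e-22, adjusted p = 0.314 with an estimated correlation), Pt (camera adjusted p = 1.2e-15, adjusted p = 0.230 with an estimated correlation) and Ta (camera adjusted p = 1.0e-14, adjusted p = 0.327 with an estimated correlation). The metallothionein list passed camera as lower than with Ag for Cu (median -0.83, adjusted p = 1.9e-06), Pt (0.00620), Ta (0.0236) and Ti (0.0470), and for none of them with an estimated correlation (0.314, 0.364, 0.371 and 0.587). Proliferation genes were higher with Ta than with Ag (median 1.41, camera adjusted p = 5.8e-15, adjusted p = 0.327 with an estimated correlation). The lists that passed with an estimated correlation too were lower than with Ag: contractile genes for Ti (median -0.54, camera adjusted p = 2.4e-14, then 0.0223), integrins and adhesion genes for Ti (median -0.09, 6.6e-05, then 0.0223) and Pt (median -0.07, 3.9e-04, then 0.0325), and matrix glycoproteins for Pt (median -0.19, 2.0e-05, then 0.0325).

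The same was asked of Cu against Pt, Ta and Ti. ACTC1 differed from Cu by -2.69 ± 0.19 with Pt, -2.11 ± 0.17 with Ta and -2.77 ± 0.19 with Ti, and LEP by -2.21 ± 0.29 with Pt and -2.04 ± 0.26 with Ta. In reads LEP was lower than with Cu by 23.7 times with Pt (95% interval 10.7 to 65.3) and 12.5 times with Ta (7.97 to 20.6). INHBB differed by -2.09 ± 0.38 with Pt and CRYAB by -2.02 ± 0.10 with Ti. GDF5 was higher than with Cu by 2.32 ± 0.22 with Pt and 2.07 ± 0.20 with Ta, KRT14 by 2.27 ± 0.22 and 2.18 ± 0.20, and MT2A by 1.71 ± 0.21 with Ta. Contractile genes were lower than with Cu for Ta (median -0.37, camera adjusted p = 7.7e-13, adjusted p = 0.0487 with an estimated correlation). They also passed camera, but not with an estimated correlation, for Pt (median -0.33, camera adjusted p = 1.1e-05, then 0.186) and Ti (median -0.50, camera adjusted p = 1.8e-13, then 0.0585). Ribosomal protein genes were higher with Pt than with Cu (median 0.62, camera adjusted p = 1.9e-18, adjusted p = 0.385 with an estimated correlation). TGF-beta and BMP genes were lower with Pt (camera adjusted p = 1.8e-04, adjusted p = 0.0409 with an estimated correlation) and Ta (camera adjusted p = 0.00207, adjusted p = 0.0487 with an estimated correlation) than with Cu.

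Between Pt, Ta and Ti fewer genes differed. With Ta, the division genes UBE2C, CDC20 and PLK1 were higher than with Pt by 1.63 ± 0.31, 1.60 ± 0.26 and 1.49 ± 0.19, and proliferation genes as a list were too (median 0.87, camera adjusted p = 5.5e-27, adjusted p = 0.182 with an estimated correlation). Matrix glycoproteins were higher with Ta than with Pt (median 0.11, camera adjusted p = 7.2e-06, adjusted p = 0.0385 with an estimated correlation). Without Pt a, where no gene passed for this pair, the adjusted p of the 3 division genes was 0.149, 0.149 and 0.102; without Pt b it was 0.0851 for UBE2C and 0.0538 for CDC20, and without Ta 3 it was 0.0583 for UBE2C. COLEC12 was higher with Ti than with Pt by 1.98 ± 0.41, a call lost without Pt a (0.158) or Pt b (0.124). WISP2 was higher with Ti than with Ta by 1.46 ± 0.21 and CHAC1 differed by -0.80 ± 0.11, and both calls were lost without Ta 1 (0.153 and 0.0791).

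By limma's moderated test 1557 genes differed between Cu and Ag, 4753 between Pt and Ag, 3433 between Ta and Ag and 2696 between Ti and Ag. The counts were 2565 between Pt and Cu, 1200 between Ta and Cu, 2238 between Ti and Cu, 504 between Ta and Pt, 254 between Ti and Pt and 15 between Ti and Ta. The median gene shifted by 0.08 for Cu, 0.19 for Pt, 0.11 for Ta and 0.14 for Ti against Ag. Against Cu the shift was 0.10 for Pt, 0.04 for Ta and 0.06 for Ti. It was -0.07 for Ta and -0.05 for Ti against Pt, and 0.03 for Ti against Ta. Median-of-ratios scaling was not run for pairs of ions, so the dependence of these counts on it is not known. The shared spread lay below that of the Ti libraries, so p-values of pairs with Ti tend to be too small. A test for any difference among the 6 groups passed for 5608 genes, or 49.5%, with the smallest p-values for CRIP1 (5.9e-10), MT1G (1.1e-09), CRYAB (1.7e-08), PLAT (6.4e-08), TM4SF20 (6.7e-08) and CNN1 (1.6e-07). Leaving out 1 library moved every pair count, but not that of the 6-group test, by over 1.5 times. Cu against Ag gave 773 without Ag 1, 911 without Ag 3, 739 without Cu 1, 732 without Cu 2, 2968 without Ti a and 2970 without Ti b. Pt against Ag gave 2389 without Pt a, and Ta against Ag 1911 without Ag 1 and 2132 without Ag 3. Ti against Ag gave 1491 without Ag 1, 1451 without Ag 3, 5441 without Ti a and 745 without Ti b. Pt against Cu gave 1391 without Cu 3, 919 without Pt a and 1338 without Pt b. Ta against Cu gave 739 without Cu 1, 629 without Cu 2, 664 without Cu 3, 734 without Ta 2, 563 without Ta 3, 2048 without Ti a and 2046 without Ti b. Ti against Cu gave 1422 without Cu 2, 1439 without Cu 3 and 3872 without Ti a. Ta against Pt gave 328 without Cu 2, 0 without Pt a, 21 without Pt b, 130 without Ta 1, 325 without Ta 2, 82 without Ta 3, 1280 without Ti a and 1278 without Ti b. Ti against Pt gave 139 without Ag 1, 151 without Cu 1, 130 without Cu 2, 1 without Pt a, 38 without Pt b, 146 without Ta 1, 806 without Ti a and 2317 without Ti b. Ti against Ta gave 4 without control 1, 4 without control 2, 6 without Ag 1, 26 without Ag 2, 4 without Cu 1, 5 without Cu 2, 5 without Cu 3, 6 without Pt a, 6 without Pt b, 0 without Ta 1, 1034 without Ti a and 634 without Ti b.

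The last comparison asked how far the responses to Ag, Cu, Pt and Ta overlapped. All 4 ions moved 197 genes the same way against control, 68 higher and 129 lower, where independent responses would give 0.0417 and 0.858. Each of the 197 needs a call for Ta, and most genes named for Ta lost theirs without control 1. The overlap was not counted again with 1 library left out. Higher in all 4 were the contractile genes ACTA2, CNN1, TPM2 and ACTG2, the small heat shock proteins HSPB1 and CRYAB, the TGF-beta and BMP targets ID3 and CTGF, and MCAM, CD200 and WNT5A. Lower in all 4 were the osteogenic RUNX2 and POSTN, the chondrogenic COL10A1 and CYTL1, the stromal CXCL12 and PDGFRA, the Wnt genes TCF7, SFRP4 and WISP1, the lysosomal CTSB, SQSTM1 and GPNMB, and HMOX1. CD14 and CD68, 2 of the 3 blood and immune markers in the table, were also lower in all 4. None of the 25 proliferation genes was among the 197, since none passed for Ta. Pairs of ions shared 400 higher and 1406 lower genes for Ag and Cu, with 24 opposite, 278 and 530 for Cu and Pt, with 28 opposite, 122 and 202 for Pt and Ta, with 0 opposite, and 199 and 441 for Ag and Pt, with 104 opposite. Ag and Ta shared 77 and 173, with 20 opposite, and Cu and Ta 121 and 244, with 3 opposite. Independent responses would give 49.2 and 606 for Ag and Cu, 52.3 and 115 for Cu and Pt, 49.4 and 206 for Ag and Pt, 9.03 and 84.5 for Ag and Ta, 9.57 and 47.2 for Cu and Ta, and 9.60 higher genes for Pt and Ta. All these comparisons used the same 2 control libraries, which cannot be split between ions, so part of the excess may come from them. In 100 simulations of unchanged groups against 2 shared controls the median number of genes moved alike by all 4 ions was 0. The highest was 3038 and the second highest 0, so 1 of the 100 gave as many as 197. That 1 was among 25 simulations in which a control took the deviation of a Ti library. In a group of 2 libraries both deviations are equal in size. With random signs, both controls could take the same deviation and so show no spread. Whether this gave the highest simulated values was not checked. The covariance of changes between ions was 0.096 for Ag and Cu, 0.089 for Cu and Pt, 0.060 for Pt and Ta, 0.050 for Ag and Pt, 0.038 for Ag and Ta and 0.069 for Cu and Ta. The simulations gave a mean of 0.013 to 0.014 and at most 0.072 to 0.082. Without the Ti libraries in the simulation, the highest values were 0.025 to 0.029, below all 6 covariances. Correlations lay above the simulated mean for Ag and Cu (0.64 against 0.56), Cu and Pt (0.67 against 0.55), Cu and Ta (0.75 against 0.55) and Pt and Ta (0.76 against 0.54), but below it for Ag and Pt (0.38 against 0.53) and Ag and Ta (0.41 against 0.58). Changes had the same sign in 78.9% of genes for Ag and Cu (68.3% simulated), 76.2% for Cu and Ta (69.3% simulated), 70.8% for Pt and Ta (69.4% simulated), 70.6% for Ag and Ta (70.8% simulated), 63.3% for Cu and Pt (69% simulated) and 55.7% for Ag and Pt (68.4% simulated). These shares and the counts of opposite genes depend on the shift of the median gene. That shift was -0.19 with Ag, -0.11 with Cu, 0.01 with Pt and -0.07 with Ta. Neither was computed after median-of-ratios scaling.

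**Figure D4:**
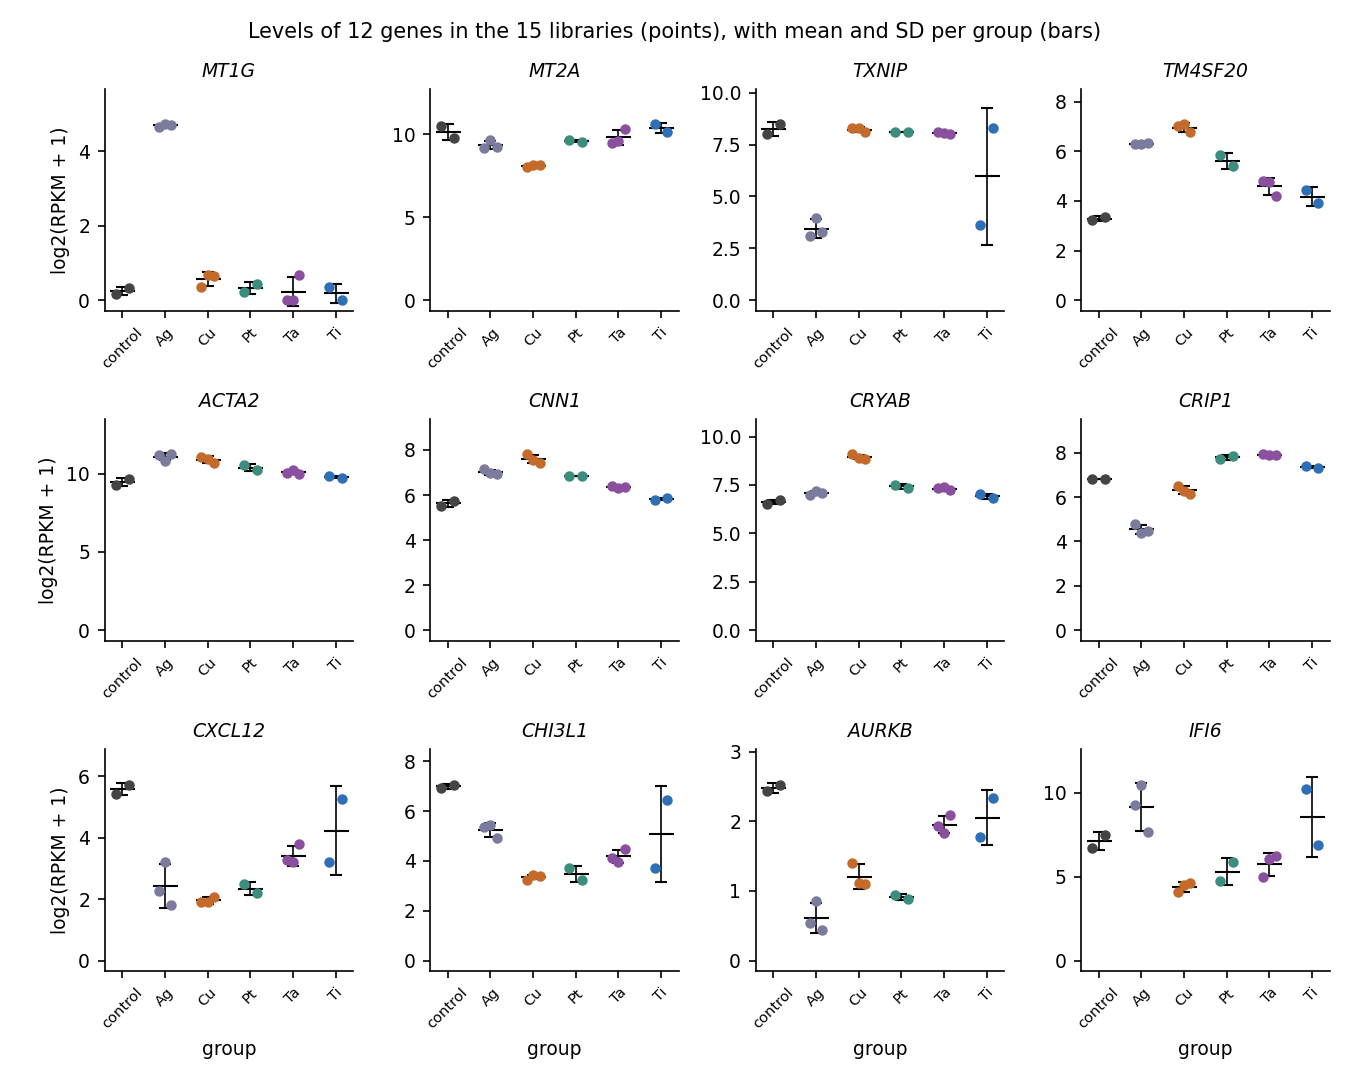
Levels of 12 genes as log2(RPKM + 1) in the 15 libraries (points), with the mean and SD of each group (horizontal mark and bar). TM4SF20 stands at 124 ± 14.0 RPKM with Cu against 8.74 ± 0.657 in control, and TXNIP at 10.3 ± 3.86 with Ag against 308 ± 70.4 in control.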

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

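The fits without both Ti libraries, with voom weights and with 4 groups without a block, the counts of genes at a log2 change of 1 or more, and median-of-ratios scaling for lists were chosen after the data were seen. The cause of the shifts below was not tested, except where fewer libraries or a stricter threshold make up the alternative. Of 209 values given for named genes 0 reversed direction, and of the 203 past the threshold 167 kept their call in every alternative run for them. Most of these genes were named for large separated changes or small p-values in the same data, so the lack of reversals says little about stability. The block and the 4 groups covered 151 of the 209, the fit on 2 groups 175, the stricter filter 171 and the fit without Ti libraries 195. The 36 others were 25 for Ta, 2 for Ag, 1 for Cu, 2 for Pt and 6 between Pt, Ta and Ti, and leaving out 1 library ended a call in each of them. The fit without a filter tested the same genes and says nothing about stability. Depth limits the genes with few reads, whose ratios are given with intervals.

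With a log2 change of 1 or more, counts fell to 332 for Ag, 348 for Cu, 173 for Pt and 51 for Ta, to 147 for Cu against Ag, 239 for Pt against Ag, 236 for Ta against Ag, 165 for Ti against Ag, 74 for Pt against Cu, 98 for Ta against Cu, 225 for Ti against Cu, 23 for Ta against Pt, 35 for Ti against Pt and 2 for Ti against Ta, and the overlap of 4 ions to 27. Median-of-ratios scaling gave 2298 genes for Pt and 1 for Ti. Without both Ti libraries the counts were 2394 for Pt, 1107 for Ta, 2971 for Cu against Ag, 2049 for Ta against Cu and 1279 for Ta against Pt. The replicate number as a block gave 850 for Ta, 2865 for Cu against Ag and 1994 for Ta against Cu, and the same 4 groups without the block gave 1043, 2926 and 2011, so the rise came with the choice of groups and the block lowered it. Libraries of the same number did not pair: their deviations correlated across genes at -0.29 to 0.30 in 15 pairs, against -0.41 to 0.41 in 30 other pairs, and 1 of 11 libraries matched its own number best. A fit on 2 groups gave 935 for Ta. Quantile normalization gave 388 for Ti against Pt and 148 for Ti against Ta, and voom 25 for the latter.

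Leaving out 1 library, with a lone library assumed to vary like the other groups, gave 1919 to 5444 genes for Ag, 1258 to 3779 for Cu, 425 to 2394 for Pt, 5 to 1108 for Ta and 0 to 1871 for Ti. Between ions it gave 732 to 2970 for Cu against Ag, 2389 to 5739 for Pt against Ag, 1911 to 4665 for Ta against Ag, 745 to 5441 for Ti against Ag, 919 to 3542 for Pt against Cu, 563 to 2048 for Ta against Cu, 1422 to 3872 for Ti against Cu, 0 to 1280 for Ta against Pt, 1 to 2317 for Ti against Pt and 0 to 1034 for Ti against Ta. The 6-group test gave 4221 to 7543.

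Of 31 lists, camera with the preset correlation called 12 for Ag, 8 for Cu, 12 for Pt, 13 for Ta and 10 for Ti. With an estimated correlation 3, 2, 0, 2 and 1 passed, and with fry 17, 15, 5, 2 and 1. Ribosomal protein genes reversed after quantile normalization for Pt (adjusted p = 0.0335) and Ti (adjusted p = 0.548). Leaving out 1 library, 3 Ti lists reversed without Ti a: YAP and TEAD targets (adjusted p = 0.726, against 2.2e-06 without Ti b), interferon response (9.8e-09, against 2.5e-05 without control 1 and 2.5e-29 without Ti b) and glycolysis (4.2e-05, against 0.635 without control 2 and 5.4e-16 without Ti b).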

Other observations

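Among the 10 genes with the smallest p-values across the 6 groups were 3 not described above. SELENOW (chr19:47778703-47784682) moved in opposite directions with Ag and Pt: its RPKM was 236 ± 15.5 in control, 115 ± 6.13 with Ag (log2 = -1.03, adjusted p = 9.3e-06) and 425 ± 11.5 with Pt (log2 = 0.85, adjusted p = 4.3e-04), with an adjusted p of 2.2e-07 across the groups. GALNT15 (chr3:16174680-16248224; adjusted p = 3.1e-07 across the groups) rose with Ag, from 2.76 ± 0.146 to 9.62 ± 1.83 (log2 = 1.48, adjusted p = 5.5e-06), and was lower with Ta at 1.59 ± 0.0315 (log2 = -0.54, adjusted p = 0.0267). LRRC15 (chr3:194355249-194369743; adjusted p = 4.2e-07 across the groups) was lower with 4 ions: from 8.59 ± 0.676 in control it fell to 0.889 ± 0.107 with Cu, 1.83 ± 0.295 with Ag, 1.79 ± 0.315 with Pt and 3.47 ± 0.153 with Ta. The calls of these 3 genes were not checked under the alternatives above. Most genes named for Ta lost their call there without control 1.

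The tests of MT1G for a wrong label, of depth in a Ti library and of a chance overlap through the position of the other Ti library were chosen only after the result was seen.

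In the 5442 genes called for Ag without the Ti libraries, 1 of these lay nearer the Ag libraries than the other did, with a median position of 0.65 on the scale from control (0) to Ag (1), against 0.83 to 1.09 for the Ag libraries and -0.12 for the other Ti library. A mislabelled Ag library was argued against by MT1G, at 0.282 RPKM (upper bound 1.02) against 24.1 to 25.6 in the Ag libraries. A mixture with Ag-treated material was argued against by MT1G, which gave a share of 0.370% (bounds -0.630 to 3.34), where genes higher with Ag gave a median of 40.3% (150 genes) and genes lower with Ag 67.0% (432 genes). Depth was argued against by 31.4 Mreads, inside the range of the other libraries. No batch was given in the sources used here, and a batch, or a true difference between cultures with Ti, was not tested.

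With Ag, 82.9% of the genes past the threshold were lower (725 higher, 3504 lower). After median-of-ratios scaling 49.5% were lower, but that scaling centres the split by construction, and without spike-ins (not given in the sources used here) it cannot tell scaling from a true loss of RNA of many genes. Leaving out the 10 most abundant genes and rescaling each library to the same sum left 71.1% lower. That step also evened out RPKM sums, which were 671180 and 644668 in control and 606362, 640220 and 600642 with Ag. The fall to 71.1% therefore cannot be credited to these genes. They held 14.5 and 14.8% of RPKM in control and 15.6, 14.4 and 15.6% with Ag, which argued against them as the whole cause. Removing trends on GC content and length left 83.6% lower, but this kept each library's level by construction, so GC content and length cannot be told apart from a true loss either.

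For 197 genes Ag, Cu, Pt and Ta changed RNA in the same direction. Each needs a call for Ta, and most genes named for Ta lost theirs without control 1. Control libraries unlike untreated cells cannot be told apart from an effect of the ions. Over 511 genes called without the Ti libraries, Ti b had a median position of 0.09 (SE 0.013) between control (0) and the 4 ions (1). Ti a lay at 0.87 (SE 0.022). By the bound set in advance, 1 Ti library below the midpoint by more than its SE counts against this explanation, and Ti b met that bound. The rule was then changed to ask this of both Ti libraries, because they differ so widely. Ti a did not meet it, so no conclusion is drawn. A chance error shared through the controls stays open too. By the test fixed in advance 197 lay within the range of 100 simulations of unchanged groups. Only 1 gave as many, with 3038, and the second highest gave 0. That 1 was among 25 simulations in which a control took the deviation of a Ti library. Both deviations of a group of 2 libraries are equal in size. With random signs, both controls could take the same deviation and so show no spread. Whether the 3038 arose this way was not checked, so this test cannot decide. The position of 0.09 is again the value of 1 library. Without the Ti libraries 0 of 100 gave as many as the 511 genes seen, with a highest value of 56, but that bound assumes controls that vary like the other groups. A batch shared by the controls and a Ti library remains open.

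Splits of 6 libraries into 3 and 3 are too few for a share under 0.05. Of 10 splits, only the real 1 gave as many genes for Cu against Ag (1557), Ta against Ag (3433) and Ta against Cu (1200), and the highest other split gave 0 in each.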
